A study of Mus musculus with 50 samples.

How the data were processed

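The labels described 50 samples in 42 groups, and values from 46 libraries were used. Poly(A) RNA was measured in mouse embryonic stem cells (mESCs) of the line TC1 treated with small interfering RNAs (siRNAs), with 2 libraries for each of siNC (the control siRNA), siEftud2, siIsy1, siLsm4, siSnrpb and siSnrpd2. The same assay covered V6.5 mESCs with siNC or siIsy1 (2 libraries each), TC1-EGFP cells at passages 0 to 15, TBLCs (the label of the cells kept in SLP medium) before and after return to serum and LIF, and a time course in 10 nM pladienolide B (PlaB), an inhibitor of the spliceosome. RNA labelled with 4-thiouridine (4sU), which marks transcripts made during the labelling, was measured in TC1-EGFP cells with 10 nM PlaB and in the human lung cancer line H1299 with 50 nM PlaB. Open chromatin (ATAC-seq) was profiled in TBLCs and in PSCs (the label of the serum and LIF cells), and single-cell RNA (scRNA) in siNC, siSnrpd2, PSC and TBLC cells and in placenta with yolk sac at embryonic days 13.5 and 14.5. Whole-genome bisulfite and ribosome profiling libraries were not analysed here. Replicates were not stated to be separate cultures, so every p measures only the spread between these libraries. Groups other than the TC1 and V6.5 siRNA groups held 1 library each.

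Several labels left room for doubt. The V6.5 libraries carried the cell line name TC1, the 6 h poly(A) library was labelled with medium lacking PlaB, the 0 h 4sU mESC library was labelled as treated, and the H1299 libraries were labelled mouse although their table held human gene symbols. What r1 and r2 stand for after the return to serum and LIF was not stated. A column of siIsy1 counts had no replicate number and was assigned to its group only. The placenta and yolk sac labels stated neither host strain, chimerism nor sorting. The 0 h column of the poly(A) table, the 1 column of per-sample values not used, matched no poly(A) sample by label. Its values equalled those of passage 0, within a relative tolerance of 1e-05, in all 21696 genes shared with the passage table, so it holds the passage 0 library. The 1 h library had been fixed as the base before the data were examined and was kept.

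Per the labels, the submitters' processing notes named HISAT2, Trimmomatic, featureCounts, Cell Ranger, Seurat and Bismark and the mouse build mm10, with no versions and no roles. The authors deposited raw counts per gene for the TC1 siRNA libraries, and raw UMI counts per gene and barcode for the scRNA libraries. The deposited V6.5 values were CPM of the reads in the listed genes. The deposited 4sU values were CPM of a larger total that was not stated, since their columns summed to between 174409 and 451173. The deposited passage, removal and poly(A) tables were named CPM, but their columns summed to more than a CPM column can (1397530 at passage 0), so their unit was treated as a signal, meaning gene counts divided by a library factor that the authors did not state. The deposited ATAC peak files held, for each peak, a fold ratio over background, -log10 p and -log10 q values and a score, from a peak caller that was not named. Low values in each normalised column were whole multiples of a single step, which gave back the reads behind each value (100.0% within 0.05 of a whole read).

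In all, 4 gene names were repeated, 2 in the removal table and 2 in the V6.5 table. Later copies were left out of the removal comparison, while the V6.5 tests kept them under a changed name. The same tables held 26 date-like names each, 52 in all, which no gene list contained. Gene spans for the ATAC peaks came from an annotation of mouse assembly GRCm38.p6, the assembly that mm10 is built on. Because that table gave no strand, both ends of a gene were searched within 2 kb.

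TC1 counts were filtered with filterByExpr, scaled by TMM and fitted with group as the only term over all 12 libraries in edgeR 4.0.16 under R 4.3.3. Each siRNA was compared with siNC by the quasi-likelihood F test, 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Printed log2 fold changes came from the edgeR fit at its default prior count, while the log2 CPM given to the list tests used a prior count of 2. Standard errors (SE) came from the 2 libraries of each group with the shared spread. For the V6.5 CPM, genes at 1 CPM or more in at least 2 libraries were tested on log2(CPM + 1) by limma-trend (limma 3.58.1). Both tests were run on simulated data with 200 changed genes. At a 3-fold change the edgeR test found between 87% and 89% of raised and between 82% and 87% of lowered genes, with between 5 and 13 false calls per comparison. At a 4-fold change the limma test found 100% with 13 false calls. In each simulation a gene had the same spread in every group, and for V6.5 all genes shared 1 dispersion. The real TC1 siNC libraries differed more from each other than the replicates of any knockdown did. These rates therefore cannot show how often genes are miscalled against such controls. Overlap between knockdowns that share siNC was set against 20 simulations of unchanged groups.

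The gene lists were fixed before the data were examined, as were the tests, the alternatives in the frozen plan and the naming rule. They covered totipotency (genes of the 2-cell embryo), pluripotency, p53 targets, the integrated stress response (ISR), spliceosome genes, immediate early genes (IEGs), maternal genes, trophoblast, ectoderm, mesoderm, endoderm, fibroblast and DNA methylation genes, and single-exon genes. The spliceosome list included the genes that the siRNAs target. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. Named genes were the targets, up to 4 totipotency and pluripotency members and 2 members of each other list with the lowest p among called genes, and the 4 largest changes in each direction at 5 CPM or more, without unnamed gene models. A few genes outside that rule are said to have been chosen after their values were seen.

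Single libraries were compared as log2 ratios of the deposited values plus 1, over genes at 1 or more in at least 1 library, with no p. Up to 4 members of each list at 5 or more, and the 5 largest ratios in each direction at 10 or more, were named (for the passages by the median over the SLP passages, for time courses by the 4 h library). List medians were ranked among 10000 random lists matched in 20 expression bins. Ratios of single libraries carry 95% counting intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. A group at 0 counts was set to a floor of 3 counts over the group, so that such folds are lower bounds. Genes of near-identical families (Zscan4, Tdpoz, Usp17l, Tcstv and many Gm models) share reads, so the level of a single member is uncertain.

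ATAC peak rows with the same chromosome, start and end were collapsed to 1 interval per library. Intervals were intersected with bedtools 2.31.1, without merging those that overlap within a library. For scRNA, cells with at least 1000 UMIs and at most 20% mitochondrial UMIs were kept, and library sums (pseudobulk CPM) and shares of cells were compared, the shares also with each cell thinned to 2000 UMIs. Named genes of the sums had 50 CPM and 20 UMIs or more. The placenta and yolk sac cells were normalised, reduced to 30 principal components on 2000 variable genes and clustered (15 neighbours, Leiden resolution 0.5) with scanpy 1.11.5 and leidenalg 0.10.2 under Python 3.11.15. A cluster took a cell type name with "-like" when at least 3 markers of a fixed list were detected, meaning found in at least 25% of its cells and at least 2-fold above the other cells. The list also had to have more of its markers among the 10 top genes than any other list, or as many and at least 2 times the detected markers. A cluster with no marker among its 10 top genes and a median depth under the libraries' own median divided by 3 took no name. Intervals for shares above 0 are exact Clopper-Pearson, and a share of 0 is given with the limit of 3 cells over the total, which limits cells with a UMI and not expression. The doublet caller marked 0.0408% of E13.5 and 0.362% of E14.5 cells and so did not work, and doublets remain. No tests were run between single-cell libraries.

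Alternatives fixed in advance were, for TC1, DESeq2 1.42.0, other scalings and filters, only the groups compared, a replicate block, leaving out each library, and a minimum fold. Further ones were other pseudocounts, filters and centring for the normalised tables, stricter peaks, other cell filters and another cluster resolution. Chosen after seeing the data were edgeR on the recovered V6.5 reads, the V6.5 list alternatives, CPM of recovered reads, the passage series without passage 10, poly(A) against passage 0, and placenta without the 5% of cells with the highest doublet score.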

Results

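RNA, open chromatin and single cells were profiled to ask how mouse embryonic stem cells change when their spliceosome is repressed, by siRNAs against its parts or by PlaB. The 12 TC1 siRNA libraries, 2 per group, held between 23237630 and 31390655 counts in genes (the fewest in siNC replicate 2), and the 4 V6.5 libraries between 18816001 and 25078585. Reads recovered from the other bulk tables ranged from 18987760 (passage 10) to 32728228 (TBLC P6 r1 in serum and LIF). The 4sU libraries held fewer reads in genes, between 6101210 and 7235014 in mESCs and between 5119532 and 6991498 in H1299. The single-cell libraries held 5332 siNC, 4152 siSnrpd2, 4139 PSC and 4534 TBLC cells, with median UMIs per cell of 26129, 18190, 22339 and 6699. In placenta and yolk sac, 4897 of 5224 barcodes were kept at E13.5 and 552 of 903 at E14.5. Counting intervals and floors cover counting error only.

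The targeted gene of each siRNA was lowered, which showed how far each knockdown went. Lsm4, part of the ring of Sm-like proteins on U6 RNA, fell from 89.3 to 11.2 CPM (log2 fold change -2.99, SE 0.19, edgeR adjusted p = 4.89e-06). Snrpd2, a core Sm protein, fell from 154.1 to 27.5 CPM (-2.49, SE 0.15, edgeR adjusted p = 1.2e-07), and Snrpb, another Sm protein, fell from 352 to 89.9 CPM (-1.97, SE 0.21, edgeR adjusted p = 8.93e-06). Eftud2, a U5 GTPase, fell from 346.7 to 96.7 CPM (-1.84, SE 0.18, edgeR adjusted p = 3.95e-05). Isy1, a factor of the catalytic complex, fell least, from 61.2 to 24.9 CPM (-1.30, SE 0.28, edgeR adjusted p = 0.00573). Its libraries stood at 15.9 and 33.9 CPM against 51.5 and 70.8 in siNC. Eftud2 also fell in siSnrpb (-0.96, edgeR adjusted p = 0.000463) and siSnrpd2 (-1.01, 0.000296), Isy1 fell in siSnrpb (-0.84, 0.0192) and siSnrpd2 (-0.86, 0.0167), and Snrpd2 fell in siSnrpb (-0.57, 0.00448), while Snrpb was at 0.01 in siSnrpd2 (edgeR adjusted p = 0.97).

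**Figure D1:**
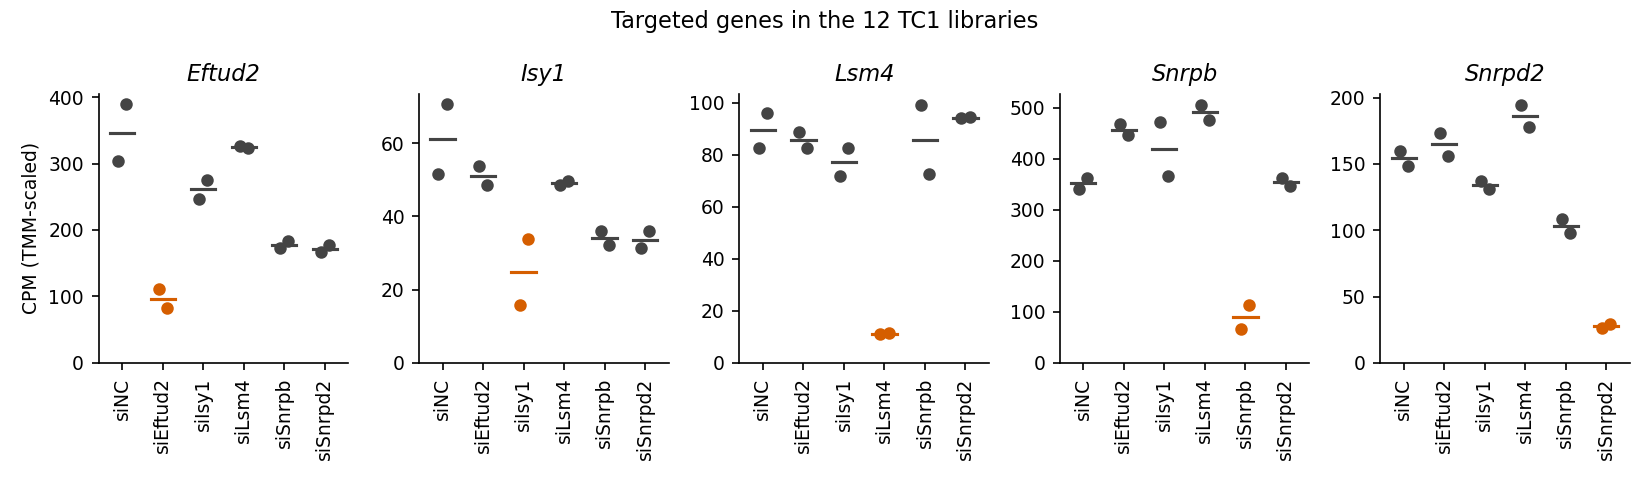
Levels of the 5 targeted genes (vertical axis, CPM scaled by TMM) in the 12 TC1 libraries grouped by siRNA (horizontal axis), with a dot per library and a line at each group's mean. Each target had its lowest group mean in its own knockdown, as with Lsm4 at 11.2 CPM against 89.3 CPM in siNC, but Isy1 in siIsy1 replicate 2 (33.9 CPM) lay above siSnrpb replicate 2 (32.2) and siSnrpd2 replicate 1 (31.4).

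The siNC libraries differed more from each other than the replicates of any knockdown did, which bears on every TC1 comparison. Their log2 CPM had a correlation of 0.974, the next lowest being siIsy1 at 0.976. Between them (replicate 1 minus replicate 2), totipotency genes had a median log2 difference of -1.45 and ISR genes one of 0.43. Maternal (0.74), endoderm (-0.63), trophoblast (0.60) and mesoderm genes (-0.56) also differed. The stress gene Chac1 stood at 123.5 and 1.86 CPM, and the endoplasmic reticulum chaperone Hspa5 at 246.5 and 1183 CPM. Pou5f1 hardly differed (-0.03). The genes in this paragraph were chosen after their values were seen. The results of all lists named here are therefore to be read with this spread in mind, and the totals were also counted without each siNC library.

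After siSnrpd2, genes of the 2-cell embryo rose and pluripotency genes fell almost throughout their lists. Of 38 measured totipotency genes 36 rose and 1 fell (36 and 1 adjusted over the list alone), with a median log2 fold change of 3.62, or 3.61 with genes at 0 in siNC set to their bound. Spz1, a testis and 2-cell transcription factor, rose by 6.11 (SE 0.51), Zfp352 by 5.21, Tdpoz4 by 5.06 (SE 0.41) and Tcstv3 by 4.20. Of 25 pluripotency genes 23 fell and 0 rose by edgeR (24 fell adjusted over the list alone; median -1.71). Pou5f1, the central factor of pluripotency, went from 1949 to 527.1 CPM (-1.89, SE 0.17), and Tdgf1, a Nodal co-receptor, from 1283 to 165.6 CPM (-2.95, SE 0.25). For p53 targets 20 of 22 rose (20 adjusted over the list alone; median 1.57), among them the cell-cycle inhibitor Cdkn1a, from 68.2 to 519.7 CPM (2.93, SE 0.17), and the death receptor Fas (6.95). Trophoblast genes rose in 11 of 13 cases (median 2.90), as with Krt8 at 2.90 and Gata3 at 3.49, and IEGs rose in 10 of 14 (2 fell; median 1.56), as with Fosl1 at 4.39. DNA methylation genes fell in 10 of 12 cases (2 rose; median -1.41), including Uhrf1 at -1.90 and Tet1 at -1.88. Spliceosome genes, the target Snrpd2 included, fell in 17 of 49 cases and rose in 1 (median -0.28), with Prpf31 at -2.0. Fgf15 (-4.66) and Gbx2 (-4.01) were among the steepest falls, and Prss34, at 0 counts in siNC, was at least 254.6-fold higher.

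In total 4503 genes rose and 4255 fell after siSnrpd2 among 16727 tested by edgeR (9708 at an unadjusted p under 0.05). The named calls had edgeR adjusted p between 9.33e-08 (Cdkn1a) and 1.95e-06 (Pou5f1) where SEs are given. Camera with the preset correlation called the totipotency (adjusted p = 2.33e-09), pluripotency (1.4e-08), p53 (1.91e-07), trophoblast (1.14e-05), DNA methylation (0.00245), IEG (0.00316) and spliceosome (0.0116) lists. These stood at adjusted p = 0.515, 0.395, 0.454, 0.283, 0.454, 0.242 and 0.769 with an estimated correlation. Without siSnrpd2 replicate 1, 2788 genes were lower, the lone library being assumed to vary like the other groups.

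After siSnrpb, the same lists moved the same way. Totipotency genes rose in 33 of 38 cases and fell in 1 (35 and 1 adjusted over the list alone; median 2.73), with Spz1 at 5.36, Zfp352 at 4.43 and Tdpoz4 at 4.29 (SE 0.40). Pluripotency genes fell in 24 of 25 cases (24 adjusted over the list alone; median -1.65). Pou5f1 went from 1949 to 557.2 CPM (-1.81, SE 0.17), and the chromatin factor Utf1 fell by 2.58 (SE 0.26). For p53 targets 20 of 22 rose (20 adjusted over the list alone; median 1.60), with Fas at 6.86 (SE 0.43) and Cdkn1a rising from 68.2 to 408.6 CPM. Trophoblast genes rose in 10 of 13 cases (median 2.75; Gata3 3.46), IEGs in 10 of 14 with 1 lower (median 1.61; Fosl1 4.59), and DNA methylation genes fell in 10 of 12 with 2 higher (median -1.40; Tet1 -1.93). Spliceosome genes, the target Snrpb included, fell in 21 of 49 cases and rose in 1 (median -0.34), with Prpf31 at -1.81. Among ISR genes 5 rose and 6 fell of 18, Atf3 rising by 3.34. Gbx2 (-3.59) and Slc9b2 (-3.38) fell furthest, and Spaca3, at 0 counts in siNC, was at least 161.7-fold higher.

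In total 4332 genes rose and 4093 fell after siSnrpb by edgeR (9459 at an unadjusted p under 0.05), with edgeR adjusted p of 1.54e-07 for Fas, 3e-06 for Pou5f1 and 2.54e-06 for Tdpoz4. Camera called the totipotency (adjusted p = 1.77e-08), pluripotency (7.85e-09), p53 (2.11e-07), trophoblast (6.1e-06), spliceosome (0.00144), DNA methylation (0.00239) and IEG (0.00958) lists. They stood at adjusted p = 0.539, 0.395, 0.454, 0.283, 0.699, 0.454 and 0.255 with an estimated correlation. Without siSnrpb replicate 1, 2635 genes were lower, and with only siSnrpb and siNC in the fit 2606 were.

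After siIsy1, totipotency genes rose although the target fell least. Of 38 members 34 rose and 1 fell (35 rose adjusted over the list alone; median 2.97), with Spz1 at 5.58 (SE 0.51), Usp17le at 4.60, Zfp352 at 4.31 (SE 0.45) and Tdpoz4 at 4.01. Of 25 pluripotency genes 14 fell and 0 rose by edgeR (17 fell adjusted over the list alone; median -0.71), such as Klf4 (-1.21, SE 0.21) and Pou5f1, from 1949 to 1047 CPM (-0.90, SE 0.17). For p53 targets 16 of 22 rose (16 adjusted over the list alone; median 1.01), and Mdm2, the ubiquitin ligase that restrains p53, went from 236.9 to 1654 CPM (2.80, SE 0.27). Endoderm genes rose in 7 of 13 cases (median 1.18), among them Gata4 at 1.35. IEGs rose in 9 of 14 (median 1.29; Fosl1 2.85), trophoblast genes in 6 of 13 (median 1.09; 8 adjusted over the list alone; Krt18 1.93), and DNA methylation genes fell in 8 of 12 (median -0.72). Besides totipotency genes, Cbln2 (5.17) and Trim75 (4.57) were among the largest rises, and Arl14epl (-2.78) and Cdx1 (-2.59) among the largest falls.

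In total 2229 genes rose and 1546 fell after siIsy1 by edgeR (6194 at an unadjusted p under 0.05), with edgeR adjusted p of 6.31e-05 for Spz1, 0.000138 for Zfp352, 0.00204 for Klf4, 0.00301 for Pou5f1 and 9.48e-05 for Mdm2. The totipotency list had a camera adjusted p of 3.53e-16 and an adjusted p = 0.454 with an estimated correlation, and the endoderm list 0.0117 and 0.559. The pluripotency, p53, trophoblast, IEG and DNA methylation lists stood at adjusted p = 0.454, 0.454, 0.38, 0.114 and 0.454 with an estimated correlation. Without the unnumbered siIsy1 library 1077 genes rose and 606 fell. With only siIsy1 and siNC in the fit 552 rose and 144 fell, and Isy1 (-1.28) and Pou5f1 (-0.88) were no longer called.

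After siEftud2, p53 targets, trophoblast genes and IEGs rose, and totipotency genes rose in part. Of 22 p53 targets 16 rose (16 adjusted over the list alone; median 1.12), with Fas at 4.43 (SE 0.42) and Cdkn1a going from 68.2 to 207.4 CPM (1.60, SE 0.16). Trophoblast genes rose in 11 of 13 cases (11 adjusted over the list alone; median 1.77), with Tfap2c at 2.10 (SE 0.17) and Gata3 at 2.70, and IEGs rose in 9 of 14 (median 1.27). Of 38 totipotency genes 22 rose (28 rose and 1 fell adjusted over the list alone; median 1.54, or 1.49 at the bound), as with Spz1 at 3.68 (SE 0.51) and Tcstv3 at 2.67 (SE 0.40). Of 25 pluripotency genes 13 fell (17 adjusted over the list alone; median -0.79), as with Zfp42 at -1.22 (SE 0.21), L1td1 at -1.05 and Tdh at -1.04. Prpf31 fell by 1.53 among 49 spliceosome genes, of which 7 rose and 2 fell, the target Eftud2 being the other that fell. Cbln2 (5.06, SE 0.43), Krt15 (4.70) and Krt5 (4.64) rose most, and Morc1 (-2.72) and Fgf17 (-2.68) were among the steepest falls.

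In total 2311 genes rose and 1985 fell after siEftud2 by edgeR (6478 at an unadjusted p under 0.05), with edgeR adjusted p of 3.87e-05 for Fas, 5.53e-05 for Cdkn1a, 0.00034 for Spz1, 0.000561 for Tcstv3 and 0.00133 for Zfp42. The p53, trophoblast, IEG, totipotency and pluripotency lists stood at adjusted p = 0.454, 0.255, 0.114, 0.559 and 0.492 with an estimated correlation. Without siEftud2 replicate 2, 941 genes rose and 485 fell (8 totipotency genes higher, 3 pluripotency genes lower), and without replicate 1, 1271 and 867 did (14 and 8). Without siNC replicate 1, 9 totipotency genes were higher.

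After siLsm4, the p53 targets rose, while the totipotency list had the lowest median and the fewest calls among the knockdowns. Of 22 p53 targets 16 rose (19 adjusted over the list alone; median 1.05), with Fas at 4.08 (SE 0.42) and Cdkn1a at 1.5 (SE 0.16). Trophoblast genes rose in 8 of 13 cases (median 1.25; Gata3 2.09, Tfap2c 1.64), and IEGs in 9 of 14 (median 0.99; Fosl1 2.7). Of 38 totipotency genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.81), with Tcstv3 at 1.87 (SE 0.40). Of 25 pluripotency genes 6 fell (8 adjusted over the list alone; median -0.37), with L1td1 at -0.89 (SE 0.20). The serine synthesis gene Phgdh (-1.43) and Asns (-1.12) fell among ISR genes, of which 5 of 18 fell and 1 rose. Cbln2 (4.80), Krt15 (4.34) and Ebf2 (3.89) were among the largest rises, and A2m (-3.34) and Camkv (-2.96) among the largest falls.

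In total 1806 genes rose and 1662 fell after siLsm4 by edgeR (5919 at an unadjusted p under 0.05), with edgeR adjusted p of 0.000164 for Fas, 0.000187 for Cdkn1a, 0.00588 for Tcstv3 and 0.00701 for L1td1. The p53, trophoblast, IEG, totipotency and pluripotency lists stood at adjusted p = 0.454, 0.283, 0.114, 0.699 and 0.699 with an estimated correlation. Without siLsm4 replicate 1, 690 genes rose and 361 fell, and Tcstv3 (1.68) and L1td1 (-0.84) were no longer called; without replicate 2, 722 and 513 did. Totipotency genes called higher numbered 2 without either siLsm4 library or siNC replicate 1, and 23 without siNC replicate 2. Pluripotency genes called lower numbered 0 and 1 without siLsm4 replicate 1 and 2, 2 without siNC replicate 2 and 10 without siSnrpb replicate 2.

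**Figure D2:**
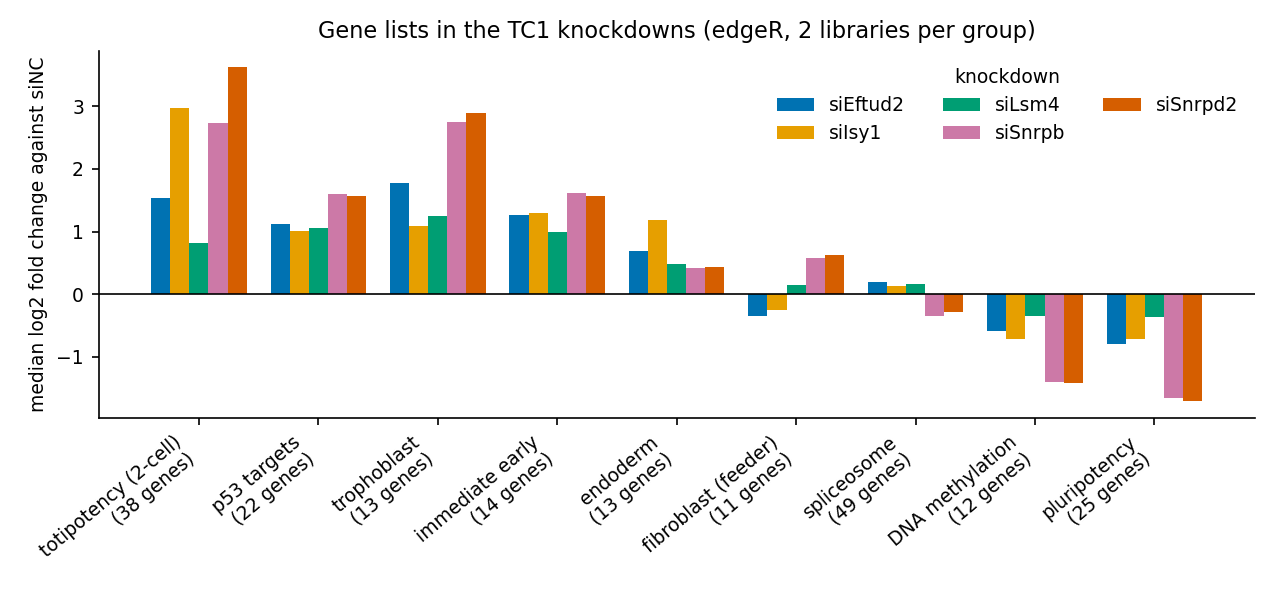
Median log2 fold change against siNC (vertical axis) of 9 gene lists (horizontal axis), a bar per knockdown, each from 2 libraries against 2. The totipotency medians ran from 0.81 in siLsm4 to 3.62 in siSnrpd2, and pluripotency medians lay below 0 in each knockdown.

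The medians of the remaining lists are given in the order siEftud2, siIsy1, siLsm4, siSnrpb and siSnrpd2. ISR medians were -0.76, -0.53, -0.56, -0.42 and -0.32, while their means in siSnrpb (0.04) and siSnrpd2 (0.15) were above 0. Maternal genes (10 measured) had medians of -0.02, -0.29, 0.13, -0.45 and 0.00, Tcl1 falling in each (-1.63, -1.76, -1.18, -2.21 and -2.35), and the list means lay above 0 (0.09, 0.21, 0.01, 0.21 and 0.49). Single-exon genes (16), which need no splicing, had medians of -0.09, 0.09, -0.21, 0.23 and 0.30. Ectoderm genes (11) had medians of -0.25, -0.15, -0.38, 0.11 and -0.32, although Zic1 rose by 4.90 in siSnrpb, and the means for siEftud2 (0.07), siLsm4 (0.08) and siSnrpd2 (0.12) had the other sign. Mesoderm genes (11) had medians of 0.47, 0.90, 0.19, 0.76 and 0.61, endoderm genes (13) of 0.69, 1.18, 0.49, 0.42 and 0.44, and fibroblast genes (11) of -0.35, -0.25, 0.15, 0.57 and 0.63. Spliceosome medians in siEftud2, siIsy1 and siLsm4 were 0.20, 0.13 and 0.17, and DNA methylation medians in siEftud2 and siLsm4 were -0.58 and -0.35. Camera called 32 of the 70 list tests over the knockdowns with the preset correlation and 0 with an estimated correlation (9 at an unadjusted p under 0.05), and fry called 29.

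The knockdowns were compared to ask which genes they share. All 5 raised 988 genes and lowered 661. Those raised in all 5 included 15 p53 targets, 8 IEGs, 6 totipotency and 6 trophoblast genes, and those lowered included 5 pluripotency, 4 ISR and 3 DNA methylation genes. The siSnrpb and siSnrpd2 libraries shared 4006 genes higher and 3705 lower, where independent lists of these sizes would share 1166 and 1041. Their log2 fold changes had a covariance across genes of 2.74 against 0.145 in simulations of unchanged groups that share siNC, so part of each overlap may come from the shared controls. The siEftud2 and siLsm4 libraries shared 1623 genes higher and 1378 lower (independent lists: 250 and 197). Set directly against siLsm4, siEftud2 differed in 1 gene higher and 1 lower by edgeR, the targets Lsm4 (2.93, SE 0.19) and Eftud2 (-1.75, SE 0.18), with 532 genes at an unadjusted p under 0.05 and 0 totipotency genes called either way. Set against siSnrpd2, siSnrpb likewise differed in 1 gene each way (342 at an unadjusted p under 0.05). Between siLsm4 and siSnrpd2 the totipotency genes did differ, with 35 lower in siLsm4 (median difference -2.45), as did 23 pluripotency genes, which were higher (median 1.22). The largest principal component held 58.1% of the variance among the 12 libraries.

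In V6.5, a second mESC line, siIsy1 raised p53 targets most clearly. All 22 p53 targets had log2 fold changes above 0 (median 1.62), 12 rose at the threshold over all genes, and 19 rose adjusted over the list alone. Mdm2 went from 124.4 to 1120 CPM (3.15, SE 0.16), and Plk2, a kinase gene induced by p53, rose by 2.5 (SE 0.14). Isy1 itself went from 59.7 (SD 16.3) to 21.9 CPM (SD 3.37, n = 2 each; -1.39, SE 0.25). Of 13 IEGs 5 rose (9 adjusted over the list alone; median 1.32), including Ccn1 at 1.94, and among 25 pluripotency genes 3 fell (7 adjusted over the list alone; median -0.45), with Utf1 at -1.61 (SE 0.18). Only 10 totipotency genes passed the filter, of which 1, Abcb5 (2.40, SE 0.27), rose (8 adjusted over the list alone; median 1.14). Trophoblast genes had a median of 0.73 with 2 of 13 higher (Krt18 2.06), and DNA methylation genes a median of -0.52 with 2 of 12 lower (5 adjusted over the list alone; Tet1 -1.13). Rgs14 (3.44), Dusp2 (3.41), Zfp750 (3.19) and P2rx7 (3.19) rose most, and Morc1 (-1.74) and Isyna1 (-1.67) were among the largest falls.

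In total 557 genes rose and 165 fell among 14200 tested by limma (4170 at an unadjusted p under 0.05), with a limma adjusted p of 0.0344 for Mdm2, Plk2, Abcb5 and Utf1 and 0.0493 for Isy1. The p53, pluripotency, IEG and totipotency lists stood at adjusted p = 0.282, 0.282, 0.282 and 0.51 with an estimated correlation, against 5.86e-11 for p53 and 0.00167 for totipotency with the preset one. Counts rested on single libraries, each lone library being assumed to vary like the others: 6325 rose and 3000 fell without siNC replicate 1, 4451 and 3960 without siNC replicate 2, 136 and 18 without siIsy1 replicate 1, and 177 and 37 without siIsy1 replicate S. Totipotency genes called higher numbered 9 without either siNC library and 0 without either siIsy1 library, and pluripotency genes called lower 17 and 13 without siNC replicate 1 and 2 and 1 without siIsy1 replicate 1. On the recovered reads edgeR called 0 genes either way, with 4171 of 15366 at an unadjusted p under 0.05. The siIsy1 effect was not tested between TC1 and V6.5.

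Cells were followed in SLP medium, which holds PlaB, to ask whether totipotency genes come on and stay on with passage. Against passage 0 in serum and LIF, totipotency genes had a median log2 ratio of 1.90 at passage 1, 4.70 at passage 6 and 4.07 at passage 15. Of 38 measured members 34 were higher at all 8 SLP passages, 25 of them at least 2-fold. Zscan4c, a telomere-associated gene of the 2-cell embryo, had a signal of 0.209 at passage 0, 28.0 at passage 1, 195.6 at passage 6 and 144.6 at passage 15 (ratio at passage 6 936, 95% counting interval 365.2 to 3437). Pluripotency genes moved later, from a median of 0.28 at passage 1 to -1.10 at passage 6, -2.14 at passage 10 and -0.51 at passage 15. Utf1 had a signal of 400.9 at passage 0, 83.2 at passage 6 and 196 at passage 15, and Tdgf1 one of 2061, 721.3 and 780.4. The p53 medians ranged from 0.37 at passage 15 to 1.36 at passage 6, with Cdkn1a at 127.4, 1195 and 407 (passages 0, 6 and 15; ratio at passage 6 9.38, 8.99 to 9.78) and Fas at 1.67, 49.9 and 31.4. Endoderm genes were highest at passage 2 (median 3.37), as with Gata6 at 4.02 at passage 0 and 136.7 at passage 1 (34, 27.1 to 43.2). Fibroblast genes were highest at passage 7 (median 3.37), and the smooth-muscle actin Acta2 stood at 41.6, 1484 and 776.5 at passages 0, 6 and 15. The DNA methylation maintenance gene Uhrf1 had signals of 849.4, 284.4 and 425.9 at the same passages.

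Over the 8 SLP passages the median log2 ratios were 4.27 for totipotency (percentile 100 among 10000 random lists), -0.54 for pluripotency (percentile 0), 2.61 for endoderm, 2.40 for fibroblast, 1.32 for single-exon, 1.01 for mesoderm, 0.99 for IEG, 0.68 for trophoblast, 0.41 for ectoderm, 0.01 for ISR, 0.00 for maternal, -0.12 for spliceosome and -0.20 for DNA methylation genes. At least 2-fold higher at all 8 passages were 509 genes, and at least 2-fold lower 17, such as Padi2 (54.9 at passage 0, 5.05 at passage 6). Without passage 10 these were 623 and 19. Each passage was 1 library, so no spread is known. Setting the recovered reads to CPM lowered the all-gene median ratio by 0.30 at passage 1 and by between 0.02 and 0.18 at later passages (shifts -0.30, -0.02 and -0.18), and the pluripotency median at passage 1 turned to -0.06 (-0.05 when centred on the median gene). With a pseudocount of 0.1 or 5 the totipotency median over passages was 7.07 or 2.22.

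**Figure D3:**
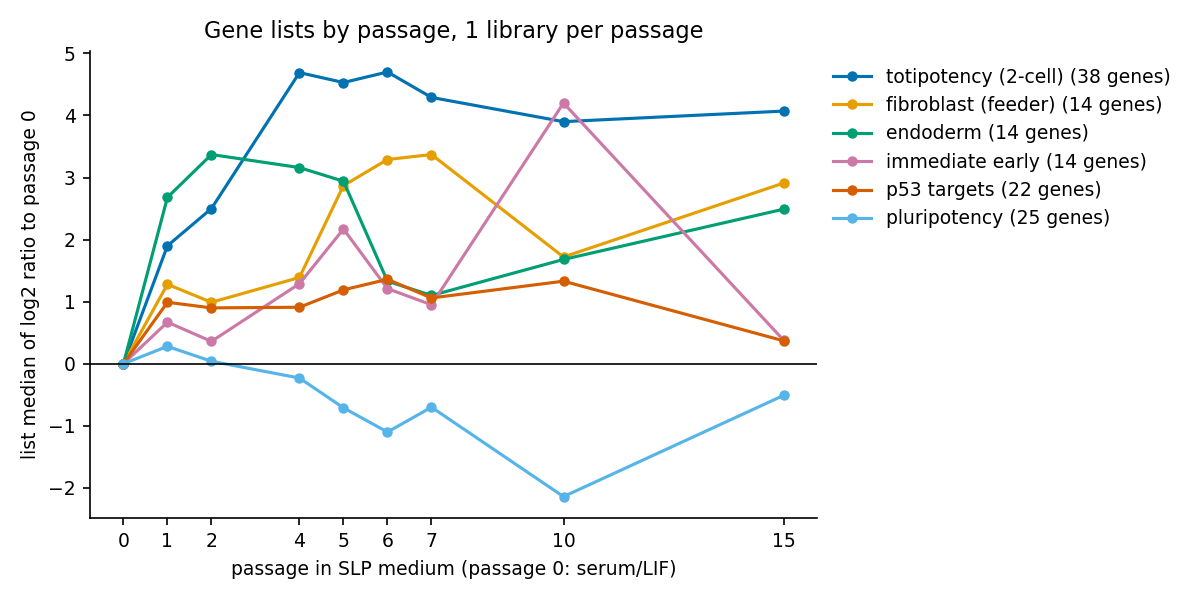
Median log2 ratio to passage 0 (vertical axis) of 6 gene lists over the SLP passages (horizontal axis), 1 library per point. The totipotency line rises from 1.90 at passage 1 to 4.70 at passage 6, while the pluripotency line is lowest at passage 10 (-2.14).

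The return of TBLCs from SLP to serum and LIF addressed whether the state reverses. Against TBLC P6 in SLP, totipotency genes were lower in both returned libraries, with median log2 ratios of -1.85 in r1 and -3.04 in r2, and 33 and 34 of 36 members were lower at least 2-fold. Usp17le had a signal of 187.7 in SLP, 30.7 in r1 and 6.31 in r2, against 0.105 at passage 0, and Zscan4d 266, 109 and 19, against 0.314. Pluripotency genes were higher (medians 1.48 and 1.28), with Pou5f1 at 757.7, 2363 and 2523 against 2400 at passage 0, and Utf1 at 89.8, 530.6 and 448.9 against 400.9. DNA methylation genes had medians of 1.02 and 0.70, with Dnmt3b at 94.1, 422.9 and 258.9. The p53 medians were -0.67 and -0.72, with Phlda3 at 387.5, 175.8 and 108.3 against 42.7 at passage 0. Fibroblast medians were -0.66 and -1.08, with Acta2 at 2560, 904.7 and 283.5 against 41.6, so passage 0 levels were not reached there. Endoderm medians were -0.20 and -1.40, spliceosome medians 0.73 and 0.42. Ifitm1 (20.8, 214.1 and 254.9) and Svep1 (83.7, 5.76 and 4.77) were among the largest differences. At least 2-fold higher were 1696 genes in r1 and 1177 in r2, and 1409 and 2267 were lower, among 15751. What r1 and r2 stand for was not stated, so their difference is not read as an order in time. With a pseudocount of 5 the totipotency medians were -1.48 and -2.13.

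Poly(A) RNA over 6 h in 10 nM PlaB showed how soon mature transcripts change. Against the 1 h library, totipotency genes had medians of 0.14, 0.56 and 0.98 at 2, 4 and 6 h (33 genes; percentile 100 at 6 h), while the all-gene medians were -0.17, -0.44 and -0.48. Tdpoz3 had signals of 0.513, 1.59, 6.0 and 12 at 1, 2, 4 and 6 h. Pluripotency genes had medians of 0.09, 0.23 and 0.41, with the growth factor gene Gdf3 at 40.5, 73.8, 134 and 183.8 and Klf5 at 264.8, 420.2, 707.8 and 723.1. Spliceosome genes had medians of 0.01, 0.27 and 0.44, with Sf3b4, a part of the complex that PlaB binds, at 172.6, 247.8, 437.5 and 573.3 (ratio at 6 h 3.32, 3.2 to 3.45), whereas Xab2 stood at 177, 121.6, 64.2 and 68.6. IEGs had medians of 0.30, -0.39 and -0.66, and Egr1 went from 1146 to 419.5, 86.6 and 35.3. The p53 medians were -0.22, -0.12 and 0.27, split between Sesn2 (387.6, 444.7, 683.4 and 898.3) and Rrm2b (25.7, 19.2, 5.22 and 2.77). Inhba (49.8 at 1 h, 534.4 at 4 h) and Bmf (65.4, 3.36) were among the largest differences. At 6 h 611 genes were at least 2-fold higher and 4014 lower among 14965, each time being 1 library. Against passage 0, which is also the 0 h column of this table, a base chosen after seeing the data, the medians at 1 and 6 h were 1.91 and 3.30 for totipotency, 1.39 and 1.56 for p53 targets and 1.69 and 0.32 for IEGs. Several signs thus depended on the base, among them those of Klf5 (-0.087) and Egr1 (0.54) at 4 h against passage 0. IEGs at 4 h were at -0.39 and 0.69 (0.05 when centred on the median gene) and at 6 h at -0.66 and 0.32, and p53 targets were at -0.22 and 1.06 at 2 h and at -0.12 and 1.36 at 4 h.

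In 4sU-labelled RNA of mESCs, spliceosome and p53 target genes were higher under 10 nM PlaB than at 0 h. Spliceosome genes had median log2 ratios of 1.03 at 1 h and 1.01 at 4 h, and 26 and 25 of 48 members were at least 2-fold higher. Snrpd2 had CPM of 17.1, 69 and 79.8 at 0, 1 and 4 h (ratio at 4 h 4.66, 4.14 to 5.27), and Snrpb 57.4, 172.4 and 216.9. The p53 targets had medians of 0.61 and 1.21 (21 members; percentiles 91.8 and 100), with Plk2 at 11.1, 26.4 and 101 (ratio at 4 h 9.08, 7.89 to 10.5) and Sesn2 at 17.4, 27.1 and 67.8, whereas Rrm2b stood at 5.79, 4.24 and 0.864. Pluripotency medians were 0.77 and 0.59, with Pou5f1 at 200.2, 597.2 and 711, and totipotency medians were 0.34 and 0.65 over 18 members, with Zscan4c at 1.37, 3.6 and 5.13. ISR medians were 0.65 and 0.69 and IEG medians 0.82 and 0.89, with Ccn1 at 3.2, 17.1 and 26.4. Zfp507 (32.3, 19.8 and 1.90) and Pkd1 (44.5, 26.5 and 5.13) were among the steepest declines, and the snoRNA host Snhg1 stood at 34.1, 100.6 and 266.2. Over 12787 genes 1746 were at least 2-fold higher and 406 lower at 1 h, and 1572 higher and 2017 lower at 4 h. The total behind the CPM was not stated, and CPM of the recovered reads shifted the all-gene median by -0.49 at 1 h and -0.41 at 4 h. Such scaling can also alter the gap between a list and the all-gene median somewhat, since 1 was added to each value. Relative to the all-gene medians, the list medians at 1 and 4 h were 0.83 and 1.08 for spliceosome, 0.41 and 1.27 for p53, 0.57 and 0.65 for pluripotency, 0.14 and 0.72 for totipotency and -0.12 at 4 h for DNA methylation genes.

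In 4sU-labelled RNA of H1299 under 50 nM PlaB, IEGs stood out and p53 targets did not. IEG medians were 0.52 at 1 h and 1.76 at 4 h (12 members, 8 at least 2-fold higher at 4 h; percentile 100). NR4A1, an orphan nuclear receptor gene, had CPM of 1.67, 8.52 and 25.7 at 0, 1 and 4 h (15.4-fold at 4 h), MYC 36.6, 91.0 and 264, and CCN1 96.1, 217.5 and 587.6. Single-exon genes had medians of 0.68 and 0.71. The p53 targets had medians of 0.12 and -0.49 over 18 members (percentiles 19.7 and 8.86), with SESN2 at 14.1, 13.1 and 2.14 and TP53INP1 at 8.98, 6.55 and 2.04, while PLK2 stood at 4.24, 19.2 and 35.6 (8.39, 7.14 to 9.92). Spliceosome medians were 0.48 and 0.16. The stress gene CHAC1 (12.9, 3.51 and 1.30) and XBP1 (10.0, 11.3 and 0.805) were lower, and NUAK2 (9.18, 28.5 and 111.4) higher. Over 12949 genes 210 were at least 2-fold higher and 134 lower at 1 h, and 239 higher and 1583 lower at 4 h. CPM of the recovered reads shifted the all-gene median by -0.32 at 1 h and -0.10 at 4 h. Relative to the all-gene medians, the list medians at 1 and 4 h were 0.33 and 2.01 for IEGs, 0.49 and 0.96 for single-exon, 0.29 and 0.41 for spliceosome, 0.26 and 0.27 for ISR, -0.07 and -0.24 for p53 and -0.13 at 4 h for DNA methylation genes.

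**Figure D4:**
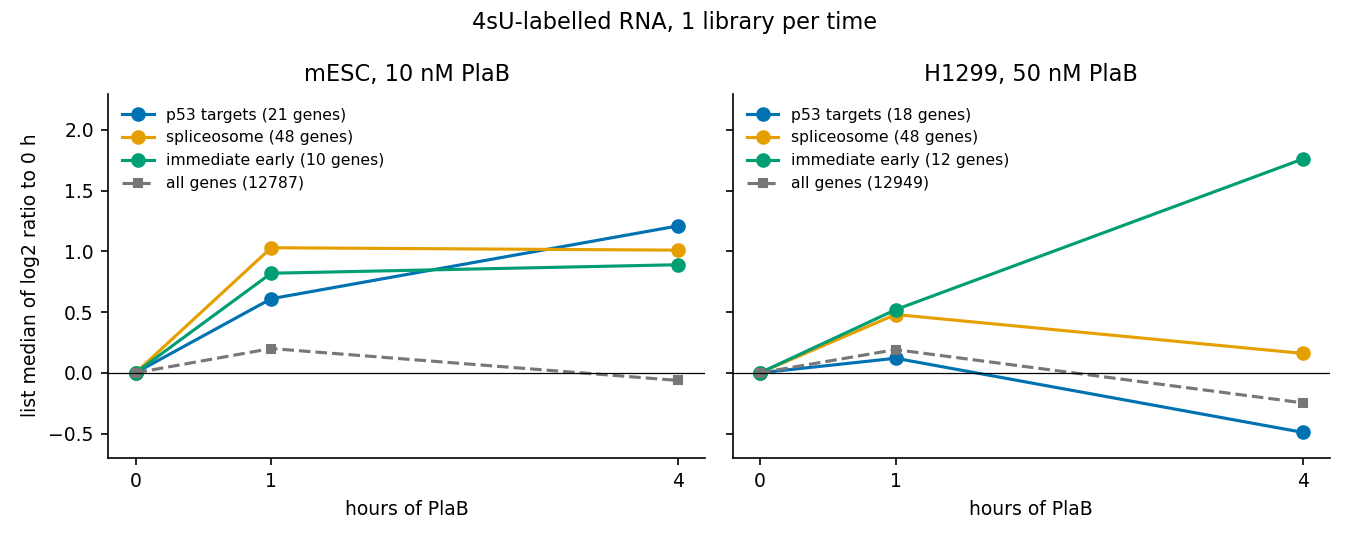
Median log2 ratio to 0 h (vertical axis) of p53 target, spliceosome, immediate early and all genes over time in PlaB (horizontal axis, h), for mESCs at 10 nM and H1299 at 50 nM, 1 library per point. At 4 h the p53 median was 1.21 in mESCs and -0.49 in H1299, and the IEG median 0.89 and 1.76.

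Open chromatin was compared between TBLCs and PSCs, 1 library each. Of 40 totipotency genes with a position, 16 had a TBLC peak within 2 kb of an end and 10 a PSC peak. Zscan4c (chromosome 7, 11005745 to 11010547), Zscan4d, Zscan4f, Usp17la, Usp17lb, Usp17lc, Gm2022, Gm8300 and Gm4027 had a peak in TBLCs alone, and Tdpoz3, Tdpoz4 and Spz1 in PSCs alone. Peaks at genes were taken from all intervals, down to a -log10 q of 0.523 in TBLCs and 0.552 in PSCs. They were not recounted with stricter intervals, so a peak in 1 library alone may be a weak one. Of all TBLC intervals 45720 overlapped no PSC interval, but only 4035 of those at a -log10 q of at least 10. All 25 pluripotency genes had a peak in both, and for all 21887 protein-coding genes the share with a peak was 76.9% in each, 485 genes having a peak in TBLCs alone and 488 in PSCs alone. The 497 genes at least 2-fold higher at every SLP passage had a peak found only in TBLCs in 21.1% of cases (17.6 to 25) against 16.7% (16.1 to 17.3) of 16061 genes, and a peak found only in PSCs in 17.3% (14.1 to 20.9) against 23.3%. TBLC peak rows collapsed to 162565 distinct intervals and PSC rows to 157239, of which 71.9% and 72.2% were shared. With a -log10 q of at least 10 the shared shares were 85.3% of 68816 and 64.5% of 90362 intervals, a gap that the unequal list lengths alone can give, and 94.1% and 88.1% overlapped any interval of the other library. Near-identical families lose reads that map to several copies, and read depth was not given.

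In single cells, siSnrpd2 was compared with siNC to ask how widely the changes spread over cells. Snrpd2 stood at 104.7 against 1031 CPM in the library sums. Of 32 totipotency genes 31 were at least 2-fold higher (median log2 ratio 3.25), with Gm8300 at 254.2 against 2.52 CPM (ratio 100.9, 91.0 to 112.1) and Sp110 at 64.9 against 0.522. Zscan4c UMIs were found in 10.5% of siSnrpd2 cells (9.54 to 11.4) and 0.488% of siNC cells, and in 4.38% and 0.113% with each cell thinned to 2000 UMIs. Of 25 pluripotency genes 19 were at least 2-fold lower (median -2.03), with Tdgf1 at 88.5 against 520.5 CPM. Pou5f1 was found in 31.9% of thinned siSnrpd2 cells against 90.7% of thinned siNC cells, Sox2 in 9.15% against 44.7% and Nanog in 2.79% against 18.5%. For p53 targets 18 of 22 were at least 2-fold higher (median 1.81), with Mdm2 at 1262 against 120.2 CPM. Endoderm genes were at least 2-fold higher in 12 of 13 cases (median 2.03; Col4a1 460.6 against 52.3 CPM) and trophoblast genes in 10 of 12 (median 2.39; Krt18 959.1 against 39.0, Krt8 859.6 against 45.2). The keratin Krt15 had the largest ratio, at 204.6 against 0.129 CPM, and Pycr2 was among the largest in the other direction, at 18.1 against 177.2. IEG, fibroblast, DNA methylation and spliceosome medians were 0.90, 1.03, -0.54 and -0.20, and the median over all 13882 genes was 0.267.

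Cells with at least 1, 5 and 10 thinned UMIs of the totipotency list made up 24.6%, 7.92% and 5.49% of siSnrpd2 and 2.59%, 0.15% and 0.113% of siNC cells. Zfp352 was found in 2.60% of thinned siSnrpd2 cells and 0 of 5332 thinned siNC cells, which allows up to 0.0563%. Median depths were 18190 and 26129 UMIs, so the siNC library was the deeper. Neither library held a cell type known to lack these genes, so the share due to free RNA is open, and each group was 1 library with no spread between libraries.

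**Figure D5:**
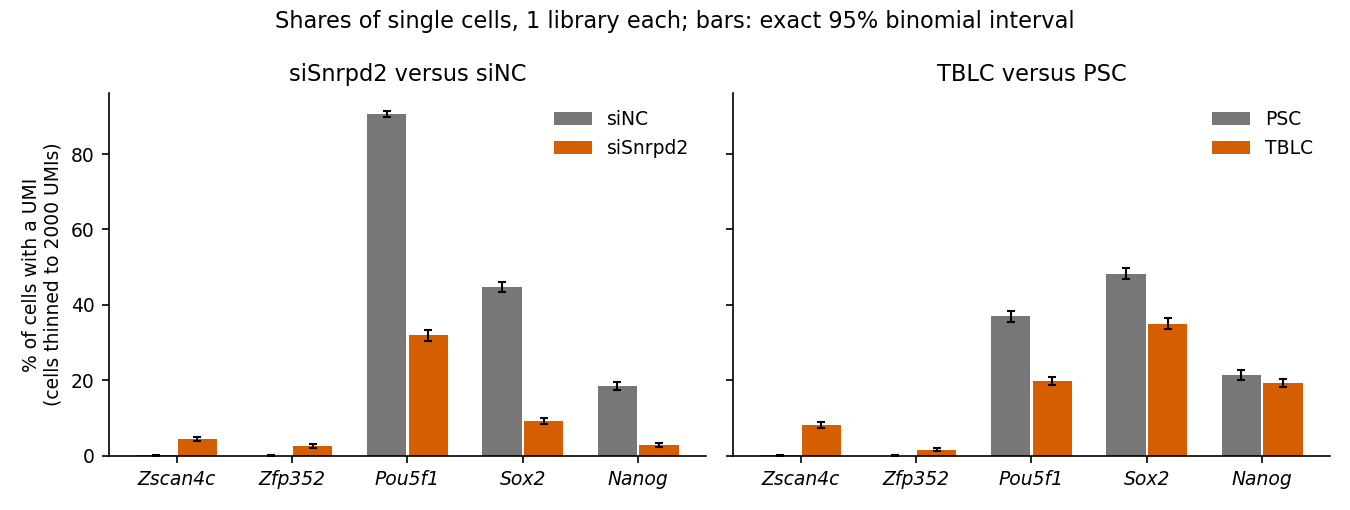
Percent of cells with at least 1 UMI (vertical axis) of Zscan4c, Zfp352, Pou5f1, Sox2 and Nanog (horizontal axis) after thinning to 2000 UMIs, with exact 95% binomial intervals, in siNC, siSnrpd2, PSC and TBLC cells. Zscan4c reached 4.38% of siSnrpd2 and 8.14% of TBLC cells, and Pou5f1 was found in fewer siSnrpd2 (31.9%) than siNC cells (90.7%).

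TBLCs were compared with PSCs in the same way. Of 33 totipotency genes 32 were at least 2-fold higher (median 2.63), with Gm8300 at 221.1 against 3.22 CPM (68.8, 61.1 to 77.6) and Sp110 at 63.7 against 0.469. Zscan4c UMIs were found in 8.14% of thinned TBLCs and 0.0725% of thinned PSCs, and Zfp352 in 3.64% of TBLCs at full depth and 0 of 4139 PSCs, which allows up to 0.0725%. Pluripotency genes had a median of -0.36, with 5 at least 2-fold lower and 1 at least 2-fold higher (20 below and 5 above PSCs in all), as Utf1 stood at 252.4 against 834.8 CPM and Dppa3, a maternal factor, at 34.2 against 1.33. Pou5f1 was found in 19.8% of thinned TBLCs against 37.0% of thinned PSCs. IEGs were at least 2-fold higher in 9 of 12 cases (median 1.65; Fos 77.2 against 6.13), trophoblast genes in 7 of 10 (median 1.81; Krt18 183.9 against 4.09), endoderm genes in 10 of 12 (median 1.63) and fibroblast genes in 8 of 11 (median 1.57). The p53 targets were at least 2-fold higher in 13 of 22 cases (median 1.09; Cdkn1a 227.4 against 40.2). DNA methylation and spliceosome medians were -0.73 and -0.25, with Uhrf1 at 43.8 against 161.5. The imprinted RNA H19 stood at 145.2 against 2.32 CPM, and Cdkn1c at 27.4 against 271.5. Cells with at least 1, 5 and 10 thinned UMIs of the totipotency list made up 49.1%, 9.73% and 6.55% of TBLCs and 2.73%, 0.145% and 0.121% of PSCs. Median depths were 6699 and 22339 UMIs, with 1 library each and no cell type that should lack these genes.

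Placenta and yolk sac cells were assigned to types by fixed markers, 1 library per embryonic day. Labyrinth trophoblast-like cells, which form the exchange surface of the placenta, made up 27.5% of E14.5 (23.8 to 31.4; 151 cells) and 0.674% of E13.5 cells (33 cells). Mesenchymal-like cells made up 24.0% (20.5 to 27.8) and 9.05% (8.26 to 9.89), and erythroid-like cells 15.3% (12.4 to 18.6) and 6.70%. The labyrinth trophoblast-like cells of both days lay in a single cluster. The mesenchymal-like and erythroid-like classes came mainly from different clusters on each day, looked at after the shares were seen. Of the E14.5 erythroid-like cells 71 were in a cluster led by the embryonic globins Hba-x, Hbb-y and Hbb-bh1, which held 8 cells at E13.5, while the other erythroid-like clusters were the more frequent at E13.5 (3.90% against 1.82%, and 2.64% against 0.545%). The largest mesenchymal-like cluster at E14.5 held 104 cells there and 87 at E13.5, where another with 275 cells was the largest (9 at E14.5). Macrophage-like cells were the more frequent at E13.5, with 15.9% (14.8 to 16.9) against 3.09% (1.81 to 4.90), as were endothelial-like cells with 7.56% against 0.364% and megakaryocyte-like cells with 6.05% against 1.09%. Trophoblast giant and spongiotrophoblast-like cells made up 0.838% and 5.09%, parietal endoderm-like cells 0.184% and 6.36%, neutrophil-like cells 1.57% and 0.182%, and mast and basophil-like cells 1.88% and 0 of 550 (up to 0.545%). Of E13.5 cells 49.6% and of E14.5 cells 17.1% took no name. Among them were 268 cells with 8 endothelial markers detected, which took none because of their low depth (median 4512 UMIs), so the endothelial-like shares are low estimates. Another unnamed cluster (140 cells at E13.5, 0 at E14.5) had Pou3f2, Hes5 and Otx2 among its top genes. A further one (92 and 1) had Phox2b, Tlx2 and Ascl1. Otx2 and Ascl1 belong to the ectoderm list. Whether the E13.5 library held tissue other than placenta and yolk sac was not tested. These clusters were picked after their genes were seen. At resolution 1.0 labyrinth trophoblast-like cells made up 0.327% and 7.64% and mesenchymal-like cells 7.72% and 10.0%. Macrophage-like cells then made up 21.3% and 4.55%, endothelial-like cells 10.9% and 1.27%, neutrophil-like cells 9.62% and 2.55%, and unnamed cells 32.7% and 32.6%. Without the 5% of cells with the highest doublet score mesenchymal-like cells made up 6.16% and 6.10%, and giant and spongiotrophoblast-like cells 8.19% at E14.5, parietal endoderm-like cells 0.687% at E13.5 and megakaryocyte-like cells 0.191% at E14.5. Pericyte and smooth muscle-like cells made up 8.72% and 0.381% in that setting. At resolution 1.0 this class held 199 of 4895 E13.5 cells (3.53% to 4.66%) and 77 of 550 E14.5 cells (11.2% to 17.2%). Its direction between the days therefore depended on the setting. Whether those E14.5 cells were mesenchymal-like at resolution 0.5 was not tested. The E14.5 labyrinth trophoblast-like cells had a median of 1920 UMIs, and day, dissection and library cannot be told apart.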

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

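Each test of an explanation below was chosen after the result was seen. The p53 target genes were singled out because their list median moved to opposite sides of the all-gene median in the 2 lines given PlaB, with 1 library per time and no test of the difference. In 4sU-labelled RNA of mESCs the list median less the all-gene median was 0.41 at 1 h and 1.27 at 4 h, whereas in H1299 it was -0.07 at 1 h and -0.24 at 4 h. How far the unstated scaling moves these values was not measured, and the H1299 value at 1 h was small. GFP was singled out because no comparison used it, and it was found in 61.9% of E13.5 cells (60.5 to 63.2) and 41.8% of E14.5 cells (37.7 to 46.1) of placenta and yolk sac, above the limit that a count of 0 allows, which any detected gene would pass, and free GFP RNA was not measured on its own.

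Sparse reads in H1299 do not explain the p53 difference, since 94.4% of its 18 p53 targets had a 4 h counting interval wholly below the mESC list median fold of 2.31, PLK2 being the exception, and the least covered member had 97 reads. Nor did the members measured explain it, since the 17 measured in both lines still gave 0.96 above the all-gene median in mESCs at 4 h (0.20 to 1.41) and -0.17 in H1299. The dose stays open, because every treated H1299 library had 50 nM PlaB and every treated mESC library 10 nM. H1299 is widely held to lack p53 protein, so a p53-dependent part of the response to PlaB may be missing there, but that was not tested, and line, species and dose cannot be told apart. CDKN1A (log2 ratio -0.62 at 4 h) and MDM2 (-0.56) in H1299 were chosen after their values were seen.

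The siSnrpb and siSnrpd2 libraries were nearly alike across genes. They were not the same cells under both names, since edgeR gave Snrpb a log2 difference of -1.98 between them (adjusted p = 0.00239) and Snrpd2 one of 1.91 (adjusted p = 7.86e-05). Lowering of both target RNAs by both siRNAs did not explain it either, since Snrpb stood at 0.01 in siSnrpd2. Snrpd2 was lower in siSnrpb, at -0.57, so a part played by lowering in that direction stays open, and protein was not measured. The shared siNC libraries were not the whole cause, because the covariance of their fold changes exceeded that of simulated unchanged groups by 2.60. Those simulations did not give siNC its larger spread. In a contrast of siSnrpb with siSnrpd2 that left siNC out, 1 gene was higher and 1 lower. That contrast alone cannot decide, since unchanged groups would also differ in few genes. Contrasts with siLsm4 left siNC out too. There siLsm4 had 2417 genes higher and 3052 lower than siSnrpb, and 2443 higher and 3116 lower than siSnrpd2. A common response to loss of a core Sm protein was not tested and stays open, as does a shared handling of these 4 libraries, which was not recorded.

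At E14.5 GFP was rare in trophoblast-like and parietal endoderm-like cells, with 8 of 151 labyrinth trophoblast-like, 1 of 28 giant and spongiotrophoblast-like and 1 of 35 parietal endoderm-like cells holding a UMI, against 76 of 84 erythroid-like and 89 of 132 mesenchymal-like cells. Fewer UMIs did not explain it in parietal endoderm-like cells, whose median of 40170 UMIs was near the 49379 of erythroid-like cells while GFP stood at 0.603 CPM (0.0153 to 3.36) against 322.6 CPM (305.2 to 340.7). Free GFP RNA as the source of the few UMIs found stays open. The highest level among the 3 classes was 1.92 CPM (0.876 to 3.64), and their intervals overlap. That overlap decides nothing, since the parietal endoderm-like and the giant and spongiotrophoblast-like cells held 1 GFP UMI each and so had wide intervals. At E13.5, 9 of 33 labyrinth trophoblast-like cells held a UMI, at 5.36 CPM (2.85 to 9.17) and a median of 63859 UMIs. No biological explanation was tested, and whether GFP-negative cells had another origin or had silenced the gene stays open, since the labels state neither chimerism nor sorting.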

How the results depend on the processing

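Alternatives named in the methods as added, namely edgeR on recovered V6.5 reads, the V6.5 list settings, CPM of recovered reads, the series without passage 10, the passage 0 base and the doublet score limit, were chosen after seeing the data; the cause of each change below was not tested unless stated. Of the tested genes across settings, 4102 values kept direction and side of the threshold, 179 fell short of it and 9 newly passed it; of the list tests 177 kept them, 44 fell short and 3 newly passed. Of the untested values, 1865 gene ratios, 536 list medians and 148 shares of cells or ATAC peaks stayed within their error, 449, 53 and 90 moved, and sign changes befell 10 genes at least 2-fold from their base and 6 medians with an interval clear of 0.

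With only the groups compared in the fit, which leaves fewer samples for the spread and a larger part of them from siNC, 1279 genes were higher in siEftud2, 552 higher and 144 lower in siIsy1, 893 and 1036 in siLsm4, and 2606 lower in siSnrpb. A log2 fold change of at least 1 as a further condition left 1345 and 1031 in siEftud2, 1340 and 525 in siIsy1, 1006 and 932 in siLsm4, 1999 lower in siSnrpb and 2291 lower in siSnrpd2. Leaving out each library in turn gave 941 to 2609 higher and 485 to 2491 lower in siEftud2, 1077 to 2419 and 606 to 2054 in siIsy1, 690 to 2191 and 361 to 2144 in siLsm4, 3100 to 4560 and 2635 to 4475 in siSnrpb, and 3417 to 4757 and 2788 to 4642 in siSnrpd2, each lowest value coming without a library of that knockdown, where the lone library is assumed to vary like the other groups. In V6.5 the same gave 136 to 6325 higher and 18 to 3960 lower, TMM 316 higher, no filter 83 lower, and edgeR on recovered reads 0 and 0 with 4171 genes at an unadjusted p under 0.05.

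Replicate numbers did not pair the TC1 libraries, and with them as a replicate block, without siIsy1 whose column lacked a number, camera called 25 of 56 lists. Over all TC1 lists the preset correlation called 32, an estimated one 0 and fry 29, and in V6.5 these were 6, 0 and 6. Of the V6.5 named genes 26 lost their call with edgeR on recovered reads, 8 without a filter and 5 with TMM.

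The passage totipotency median was 7.07 and 2.22 with a pseudocount of 0.1 and 5. The passage 1 pluripotency median changed sign to -0.052 when centred and -0.055 as CPM of recovered reads. After return to serum and LIF, the totipotency median was -3.28 and -2.13 in r2 with a pseudocount of 0.1 and 5, and -1.48 in r1 with 5. Poly(A) totipotency at 4 h was 0.35 with a pseudocount of 5, 1.00 centred and 2.75 against passage 0, and the IEG median turned to 0.053 centred and 0.70 against passage 0 at 4 h and to 0.32 at 6 h. The p53 medians, whose intervals held 0, also turned against passage 0, to 1.06 at 2 h and 1.36 at 4 h, as did the single-exon medians with such intervals, to 1.39, 0.77 and 1.07 at 2, 4 and 6 h. Against passage 0 at 4 h, another base changed the sign of Klf5 (-0.087), Fas (0.068), Btg2 (1.38), Jun (0.29), Junb (0.62), Jund (1.24), Egr1 (0.54), Egr2 (0.56), Fosb (3.01) and Esx1 (0.94). The H1299 pluripotency median at 1 h, over 4 genes, turned from 0.19 to -0.072 as CPM of recovered reads. Without passage 10, 623 genes were at least 2-fold higher at every passage and 19 lower.

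At a -log10 q of 5 TBLCs had 98714 intervals, with 82.2% of them and 67.3% of PSC intervals shared; at 10 there were 68816 and 90362, with 85.3% and 64.5% shared; and an overlap of 50% of the shorter peak gave 71.0% and 71.4%. At resolution 1.0 labyrinth trophoblast-like cells made up 0.327% of E13.5 and 7.64% of E14.5 cells and mesenchymal-like cells 7.72% and 10.0%, while neutrophil-like cells made up 9.62% and 2.55%, endothelial-like 10.9% and 1.27%, macrophage-like 21.3% and 4.55% and unnamed cells 32.7% and 32.6%. Giant and spongiotrophoblast-like cells at E14.5 made up 8.19% without the 5% with the highest doublet score and 8.35% from 500 UMIs, and without those 5% parietal endoderm-like cells at E13.5 made up 0.687% and megakaryocyte-like cells at E14.5 0.191%. Mesenchymal-like cells made up 6.07% and 6.52% with doublets kept, 6.16% and 6.10% without the 5% with the highest doublet score, and 7.59% and 8.94% from 500 UMIs. Depth limits the E14.5 shares, with 550 cells, and in the single-library tables no spread between cultures is known.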

Other observations

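The control siRNA libraries of TC1 differed in stress genes. Replicate 1 had higher levels of Chac1 (log2 difference 6.0), Atf3 (2.71), Herpud1 (2.65), Ddit3 (2.38) and Trib3 (1.96), and replicate 2 had higher levels of Hspa5 (-2.26), Zscan4f (-2.18) and Zscan4c, which stood at 6.55 and 20.45 CPM. By list, the median difference was 0.74 for maternal, 0.60 for trophoblast, -0.63 for endoderm and -0.56 for mesoderm genes. These genes were chosen after their values were seen.

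Passage 10 stood apart for immediate early genes, whose median log2 ratio to passage 0 was 4.20 with all 14 members at least 2-fold higher, against 0.95 at passage 7 and 0.38 at passage 15. Chac1 and Hspa5 moved in opposite directions over the passages, with signals of 171.5 and 349.8 at passage 0 and of 10.5 and 1786 at passage 6. The SLP passage 6 library and the TBLC P6 library had a correlation of 0.973 across genes, against 0.988 for SLP passages 6 and 5 of the same table. Whether these libraries came from separate cultures was not stated, so they were not treated as independent replicates.

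Genes lower at every SLP passage (1372 with a position) had a peak found only in PSCs in 25.3% of cases (23 to 27.7) against 23.3% of all genes, and one found only in TBLCs in 14.7% (12.9 to 16.7) against 16.7%. These peaks were again taken from all intervals, weak ones included.

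Cells with at least 5 thinned UMIs of the totipotency list differed from the rest of their library in other genes too. In siSnrpd2, Krt8 was found in 32.2% of these cells and 50.7% of the others, Krt18 in 30.7% and 51.4%, Mdm2 in 86.0% and 79.5% and Klf4 in 21% and 14.8%. In TBLCs, Sox2 was found in 19.7% and 36.7% and Zfp42 in 48.1% and 69.3%, whereas Krt8 (27.0% and 24.4%) and Krt18 (22.2% and 21.3%) hardly differed and Klf4 differed the other way (14.3% and 22.7%). These genes were chosen after their values were seen, and no test was run.

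Of 62 genes named in either siIsy1 comparison and measured in both lines, 51 had siIsy1 libraries apart from siNC on the same side in TC1 and V6.5, 0 on opposite sides, and 11 overlapped in at least 1 line. Apart from the targeted genes, which were named whatever their p, these genes were chosen among those called in at least 1 line. For 2 libraries against 2, a gene apart in 1 line has a 16.7% chance of lying apart on the same side in the other. Genes of the same libraries move together, so the 62 are not separate trials. Their 51 therefore cannot be weighed against that figure, and the share over all genes measured in both lines was not counted. The lines were not tested against each other.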
